A study of Mus musculus with 35 samples.

How the data were processed

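RNA of sorted CD8 T cells from mouse brain and spleen was measured in 35 libraries of 7 groups, taken from the sample labels. The authors aligned reads with Bowtie2 2.2.0 and quantified genes with RSEM 1.2.12 on the mouse build mm10, per the submitters' processing notes; the annotation release and the use of strand are not given in the sources used here. Per the file headers, the authors deposited RSEM expected counts for each library, which need not be whole numbers. Per the file headers, the authors' TPM values are RSEM's transcript abundances scaled within each library, and they were not used in a test. Per the file headers, the authors' FPKM values are RSEM's fragment counts scaled by gene length and library size, also not used in a test. The deposited table of the whole series holds whole-number counts for 38924 genes, which differ from the expected counts by at most 0.5, as rounding gives. These counts entered the main tests, and the expected counts of the sample files, rounded, were an alternative. RSEM shares reads between similar genes, so near-identical copies such as Hspa1a and Hspa1b, histone, ribosomal protein and Klra genes, their pseudogenes, and T cell receptor and immunoglobulin segments have uncertain single values. Without a stated strand, overlapping and antisense genes are uncertain too. Gene symbols came with the files, and 359 table entries share a symbol with another. Positions are from GENCODE M21 on GRCm38, the assembly also called mm10, where 37607 identifiers (96.6%) were found.

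Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, with a minimum count of 10, and scaled by TMM. The quasi-likelihood test (glmQLFit with robust settings, glmQLFTest, two-sided) was fitted to the groups compared only, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Differences between responses to stimulation were interaction contrasts over 4 groups. CPM values use TMM-scaled totals with 2 exceptions. The 50.1 CPM of Ddx3y in stimulated male brain replicate 19 uses an unscaled total. So do the CPM of brain cell markers and Ttr on which list scores were regressed. Lists of 29 gene groups and cell type markers, fixed before the data were examined, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison with at least 3 measured members; the p given beside a list is this adjusted value. Camera with an estimated correlation was the alternative. Text genes followed a rule fixed at the same time: Cd200r1, up to 3 members per list and direction with the largest change among those past the threshold and with a mean of at least 5 CPM, up to 2 abundant members of lists with none, the 6 highest and 6 lowest changes with a mean of at least 10 CPM and no overlap between groups, the 5 smallest adjusted p per direction for interactions, and sex-linked genes in the sex comparisons. Symbols of predicted genes, small RNA and receptor segments were left out of the ranked part. Some genes this rule names are not reported here. Genes named only to describe the markers, the ribosomal protein genes or single libraries were chosen after their values were seen. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library, which covers counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

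Library totals ran from 1.16 to 25.0 M counts, so 1 count is worth very different CPM values across libraries. No 2 libraries of a group were alike within counting noise (smallest chi-square per degree of freedom 13.8). Each test was checked on simulated counts with 200 changed genes, drawn from the means and library sizes of the libraries compared. At a log2 fold change of 3 it recovered 90% of changed genes in the spleen stimulation comparison, 20% for tissue and 19% for age in unstimulated male brain, 12% for sex in unstimulated brain, 1% for sex in stimulated brain and for stimulation in male brain, and 0% in the other 4 comparisons. At a log2 fold change of 1 it recovered 36% in spleen and 0% elsewhere, and it called at most 7 unchanged genes. All groups of a comparison were drawn with the same spread per gene, while the real groups differed in spread and in genes detected. The recovery and the few false calls therefore need not hold for the real libraries. Alternatives planned before the data were examined were DESeq2 1.42.0 size factors, the DESeq2 test, limma voom with quality weights, other low-count filters, a fit of all 35 libraries, a minimum log2 fold change of 1, a covariate of microglia markers, sample title formats, each library left out, and the sample files as input. Leaving out mitochondrial genes, requiring detection in every library of a group, and requiring at least 10 counts in every library were added after the data were seen.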

Results

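The measurements were RNA sequencing libraries made from total RNA of CD8 T cells from C57BL/6 mice. Cells were sorted as CD3e+CD8+CD44hiCD62Llo, the surface phenotype of antigen-experienced effector memory T cells, from brain or spleen. They were left unstimulated or held for 2 h with PMA and ionomycin, a phorbol ester and a calcium ionophore that together activate T cells without engaging the T cell receptor. The 35 libraries fell into 7 groups. Unstimulated brain cells came from young males (n = 5), aged males (n = 6) and aged females (n = 5). Stimulated brain cells came from aged males (n = 4) and aged females (n = 5). Spleen cells came from aged males, unstimulated (n = 5) and stimulated (n = 5). Library totals ran from 1.16 to 24.97 M counts. Means per group were 18.4 M in aged male, 13.9 M in young male and 10.9 M in aged female unstimulated brain. Spleen means were 10.55 M unstimulated and 9.51 M stimulated, and stimulated brain libraries held 5.27 M in females and 3.41 M in males. The sample titles were sorted into 3 sets, called title formats A, B and C here. Titles of C are written without hyphens. Those of A and B are written alike, with hyphens, and the split between them is inferred, since the numbers after S in these titles repeat. Format A covered unstimulated male brain. Format B covered unstimulated female brain, stimulated male brain and 3 stimulated female brain libraries. Format C covered the other 2 stimulated female brain libraries and all spleen libraries. Where compared groups differ in title format, a difference between preparations cannot be told apart from the named contrast. The labels do not say whether replicates were separate animals, so p-values measure the spread between these samples, which may be technical.

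Brain libraries were sparser than spleen libraries, and stimulated brain libraries were the sparsest. Genes with at least 1 count numbered 15009 ± 164 (SD, n = 5) in unstimulated spleen and 14084 ± 448 (n = 5) in stimulated spleen. In unstimulated brain the numbers were 10257 ± 698 (n = 6) in aged males, 9864 ± 242 (n = 5) in young males and 9554 ± 2281 (n = 5) in aged females. They were 5578 ± 1255 (n = 5) in stimulated female brain and 3400 ± 932 (n = 4) in stimulated male brain. Mitochondrial genes took 58.6% ± 10.8 of counts in stimulated female brain and 56.3% ± 13.2 in stimulated male brain. Their share was 10.5% ± 1.65 in unstimulated female brain, 9.88% ± 0.456 in unstimulated aged male brain, 11.8% ± 1.05 in unstimulated spleen and 16.3% ± 2.53 in stimulated spleen. The median Spearman correlation between replicates of a group was 0.948 and 0.919 in unstimulated and stimulated spleen. It lay between 0.557 and 0.623 in the unstimulated brain groups and was 0.457 and 0.395 in stimulated female and male brain. Sex-linked genes checked the labels. The X inactivation RNA Xist (chromosome X, 103460366 to 103483254, GRCm38, a long non-coding RNA) was at 140 ± 27.1 CPM in unstimulated female brain and 9.11 ± 11.2 CPM in unstimulated aged male brain, where replicate 8 had 30.7 CPM of Xist and the others 0 to 11.5 CPM (mean 4.79 CPM without it). The Y-linked RNA helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) had 0 counts in all 10 female libraries and counts in all 21 male unstimulated or spleen libraries. In stimulated male brain, replicate 19 had 50.1 CPM of Ddx3y, and replicates 20, 21 and 22 had 0 counts of Ddx3y, Uty, Kdm5d, Eif2s3y and Xist. Stimulated female brain replicate 27 had 0 counts of Xist as well as of Ddx3y, so these 4 libraries gave no check.

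**Figure D1:**
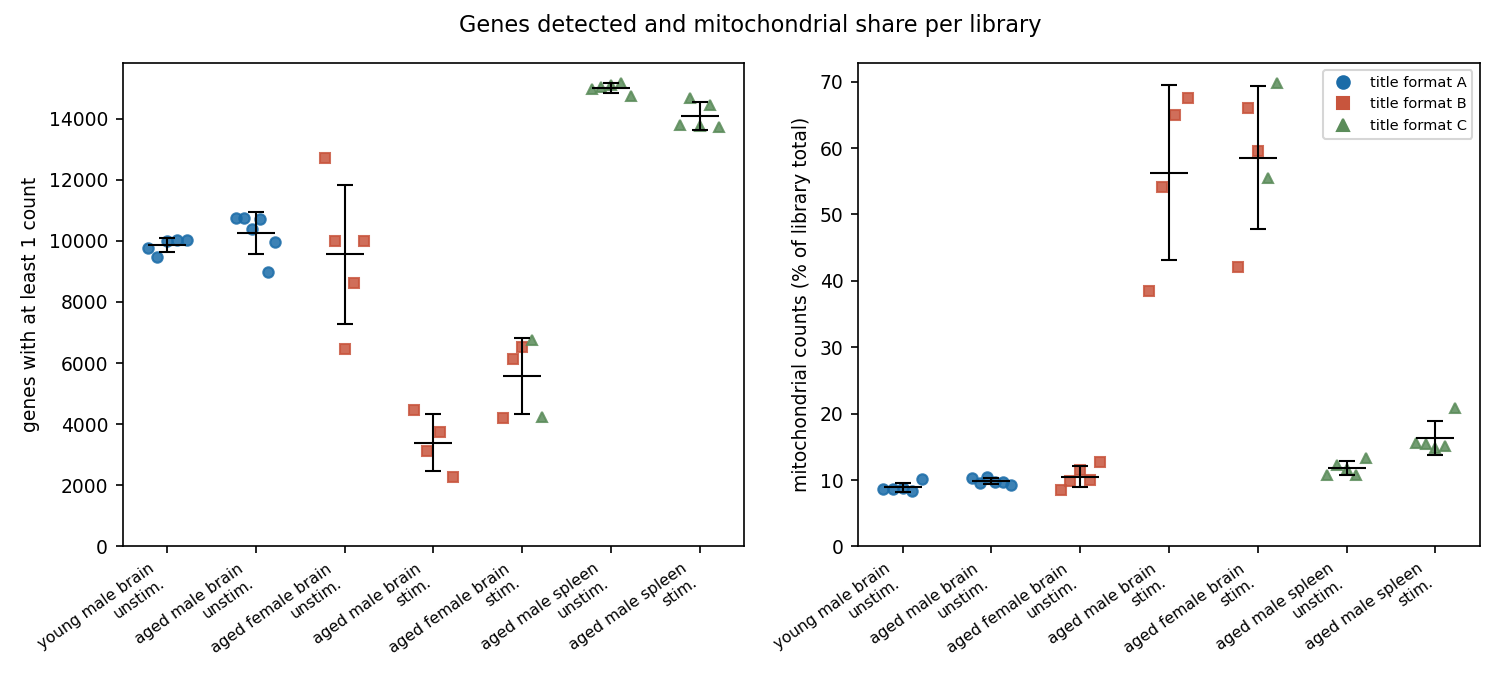
Genes with at least 1 count (left) and mitochondrial counts as a percentage of the library total (right), for each of 35 libraries; horizontal bars are group means and error bars 1 SD, and symbols give the sample title format. Stimulated brain libraries detected the fewest genes (means 5578 in females and 3400 in males) and carried mitochondrial shares between 38.5% and 69.7%.

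Aged male brain and spleen cells were compared without stimulation to describe what sets brain CD8 T cells apart. Genes of recent activation and of tissue retention were higher in brain cells. The orphan nuclear receptor gene Nr4a1, an immediate early gene (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795, GRCm38, protein-coding), reached 1013 ± 759 CPM (SD, n = 6) in brain and 5.49 ± 1.497 CPM (n = 5) in spleen, a log2 fold change of 7.53 ± 0.54 (SE, adjusted p = 7.6e-07). Tnfaip3, which encodes a brake on NF-kB signalling (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657), had a log2 fold change of 4.43 ± 0.18 (adjusted p = 1.9e-09). Among the lower genes were Klrg1, an inhibitory receptor of terminally differentiated T cells, with a log2 fold change of -8.91 ± 1.48, and the sphingosine-1-phosphate receptor gene S1pr5, which serves exit from tissue, with -7.93 ± 1.51. With edgeR's quasi-likelihood test, 814 of 11040 genes passed an adjusted p of 0.05, 370 higher and 444 lower in brain. All 214 tested genes with 0 counts in all 6 brain libraries were among the lower ones. The median log2 fold change of all genes tested was 0.31.

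Of 24 immediate early genes measured, 15 were higher in brain and none lower, and 19 passed when adjusted over the list alone (camera adjusted p = 8.3e-31, and 0.00092 with an estimated correlation). Nr4a3 (6.40 ± 0.37) and Nr4a2 (5.79 ± 0.38), relatives of Nr4a1, Fosl2, an AP-1 subunit (6.15 ± 0.37), and Atf3, a stress-induced transcription factor (9.19 ± 1.88), were among them. Among 12 heat shock genes 9 were higher, and 11 when adjusted over the list alone (adjusted p = 6.4e-14, and 0.0056 with an estimated correlation). Hspa1a rose to 1409 ± 533 CPM in brain against 66.7 ± 59.5 CPM in spleen (log2 fold change 4.402 ± 0.66), Hspa1b by 4.25 ± 0.55 and Hsp90aa1 by 1.93 ± 0.27. Hspa1a and Hspa1b are near-identical copies, and the split of reads between them is uncertain. Among 19 tissue residency genes 6 were higher, and 12 when adjusted over the list alone (adjusted p = 5.3e-11, and 0.00092 with an estimated correlation). These included Rgs2, a regulator of G protein signalling (4.77 ± 0.29), Cdh1, which encodes E-cadherin (3.86 ± 0.44), and Cd69, whose product retains T cells in tissue and also marks activation, at 291 ± 414 CPM against 23.6 ± 12.4 CPM (3.63 ± 0.79, adjusted p = 0.0078). Brain replicate 8 alone had 1128 CPM of Cd69, and without it the mean was 124 CPM (log2 fold change 2.40, adjusted p = 0.0088). Among 23 interferon response genes 6 were higher, and 15 when adjusted over the list alone (adjusted p = 2.6e-10, and 0.00092 with an estimated correlation), with Ifit3 at 3.56 ± 0.44, Ifit1 at 3.33 ± 0.66 and Rtp4 at 2.80 ± 0.55. The 3 cell death genes of 16 that were higher included Tnfrsf1b (2.49 ± 0.35) and the survival gene Bcl2 (1.72 ± 0.35), with 4 when adjusted over the list alone (adjusted p = 0.0061, and 0.047 with an estimated correlation).

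Some T cell and effector genes were higher in brain cells too, a minority of each list. Among 16 CD8 T cell identity genes 4 were higher, and 5 when adjusted over the list alone (adjusted p = 0.00053, adjusted p = 0.075 with an estimated correlation). Cd8a stood at 911 ± 256 CPM in brain and 320 ± 26.8 CPM in spleen (1.51 ± 0.21), Cd3g at a log2 fold change of 1.32 ± 0.20 and Cd2 at 0.95 ± 0.19. Pdcd1, which encodes the inhibitory receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), was at 165 ± 92.4 CPM against 25.9 ± 15.3 CPM (2.67 ± 0.54, adjusted p = 0.0049). The inhibitory receptor and exhaustion list had 2 of 20 genes higher and 1 lower, and 6 higher and 1 lower when adjusted over the list alone (adjusted p = 0.024, adjusted p = 0.075 with an estimated correlation). Cytotoxic genes had 3 of 15 higher, Serpinb9 (2.28 ± 0.38), Fasl (1.91 ± 0.48) and Tnfsf10 (1.66 ± 0.47), and 5 when adjusted over the list alone (adjusted p = 0.012, adjusted p = 0.075 with an estimated correlation). Ifng, the interferon gamma gene, was at 187 ± 141 CPM against 18.6 ± 4.94 CPM (3.33 ± 0.68, adjusted p = 0.0051), the only member of 14 cytokine and chemokine genes past the threshold over all genes, with 3 when adjusted over the list alone (adjusted p = 0.088). NF-kB and NFAT target genes had 3 of 23 higher, Tnfaip3, Nfkbid (3.18 ± 0.87) and Nfkbiz (2.84 ± 0.58), also 3 when adjusted over the list alone (adjusted p = 0.055). Trafficking receptor genes had 2 of 21 higher, Cxcr4 (3.40 ± 0.42) and Selplg (0.79 ± 0.21), also 2 when adjusted over the list alone (adjusted p = 0.054). Cell cycle genes had 3 of 19 higher, Stmn1 (2.50 ± 0.49), Top2a (2.13 ± 0.57) and Pcna (1.49 ± 0.27), with 5 when adjusted over the list alone (adjusted p = 0.10). None of 15 glycolysis genes passed either way, while the list as a whole lay higher (adjusted p = 0.012, adjusted p = 0.075 with an estimated correlation). Age-associated CD8 genes had 1 of 10 higher, also 1 when adjusted over the list alone (adjusted p = 0.16).

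Some circulation and naive-state genes were lower in brain. Circulation and egress genes had 2 of 16 lower, Klrg1 and S1pr5, and 1 higher, Ly6c2 (1.49 ± 0.37), with 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0061, adjusted p = 0.068 with an estimated correlation). Naive and central memory genes had 3 of 13 lower, Slamf6 (-6.77 ± 1.49), Dapl1 (-6.19 ± 1.32) and Actn1 (-4.33 ± 1.16), with 6 when adjusted over the list alone (adjusted p = 0.0095, adjusted p = 0.075 with an estimated correlation). Genes with 0 counts in all 6 brain libraries included the proenkephalin gene Penk (chromosome 4, 4133531 to 4138819), at 41.1 ± 4.04 CPM in spleen and at least 190-fold lower in brain against a floor of 3 counts per library. Igj, the immunoglobulin joining chain gene, was at least 94.9-fold lower, the integrin gene Itgad at least 82.4-fold and the receptor gene Gpr15 at least 68.0-fold. Zdhhc13 (-9.19 ± 1.45) and Fancl (-8.78 ± 1.58) followed. High log2 fold changes besides those of Atf3 and Nr4a1 belonged to Ttr, the transthyretin gene of choroid plexus, at 242 ± 291 CPM against 0.011 ± 0.024 CPM (13.35 ± 1.64), and Ier5l (6.99 ± 1.14). Cd200r1, which encodes the inhibitory receptor named in the title of the series (ENSMUSG00000022667, chromosome 16, 44765736 to 44794978, GRCm38, protein-coding), was at 24.3 ± 40.2 CPM in brain and 6.10 ± 2.16 CPM in spleen and did not pass (2.00 ± 1.56, adjusted p = 0.62). Brain replicate 7 had 97.1 CPM of Cd200r1, the brain mean without it was 9.77 CPM, and 4 of 6 brain libraries (at most 1.60 CPM) lay under every spleen library (at least 3.60 CPM).

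Markers of other cells were measured in the same libraries. None of 12 microglia markers was higher and 1 was lower, with the same counts when adjusted over the list alone; the list's median log2 fold change was 0.96 while its test pointed down (adjusted p = 0.92). The 3 oligodendrocyte markers (Mbp 0.92 ± 0.54, adjusted p = 0.95 for the list) and 3 endothelial markers (adjusted p = 0.46) had no member past the threshold. The 3 astrocyte markers had none over all genes and 1 when adjusted over the list alone (Apoe 188 ± 376 CPM against 28.4 ± 13.2 CPM; adjusted p = 0.16). Of 4 neuron markers only Thy1, which T cells express too, was higher (0.80 ± 0.21; adjusted p = 0.45 for the list). B cell markers had 1 of 4 lower, Ighm (-5.52 ± 1.002), with 2 when adjusted over the list alone (adjusted p = 0.0053, adjusted p = 0.083 with an estimated correlation). CD4 and regulatory T cell markers had 1 of 6 lower, Ikzf2 (-3.77 ± 1.05; adjusted p = 0.013, adjusted p = 0.079 with an estimated correlation), and antigen presenting cell markers had 1 of 7 lower, Ciita, with 0 counts in brain and at least 25-fold lower (adjusted p = 0.011, adjusted p = 0.076 with an estimated correlation). Klra7 among 4 NK cell markers (-6.68 ± 1.16; adjusted p = 0.089), Tcrg-C1 among 3 gamma delta T cell markers (-6.06 ± 1.24; adjusted p = 0.52) and Hba-a2, the single red blood cell marker measured (-6.24 ± 1.31), were lower. The 4 neutrophil and monocyte markers had none past the threshold over all genes (adjusted p = 0.88), and neither did the 5 sex-linked genes (adjusted p = 0.088). Brain libraries had title format A and spleen libraries format C, so tissue and format cannot be told apart. The count of 814 became 1615 with limma voom (425 higher, 1190 lower), 1677 without a low-count filter (395 higher, 1282 lower) and 641 in a fit of all 35 libraries (77 higher, 564 lower). The balance turned with DESeq2 (608 higher, 538 lower), with a minimum of 1 CPM (357 higher, 326 lower) and, with 193 higher and 52 lower, among the 4168 genes with at least 10 counts in every library, a filter added after the data were seen. Without spleen replicate 31, 9 of the 53 named genes past the threshold lost it, among them Ly6c2, Fasl, Tnfsf10, Selplg, Nfkbid, Top2a, Thy1, Ikzf2 and Actn1.

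**Figure D2:**
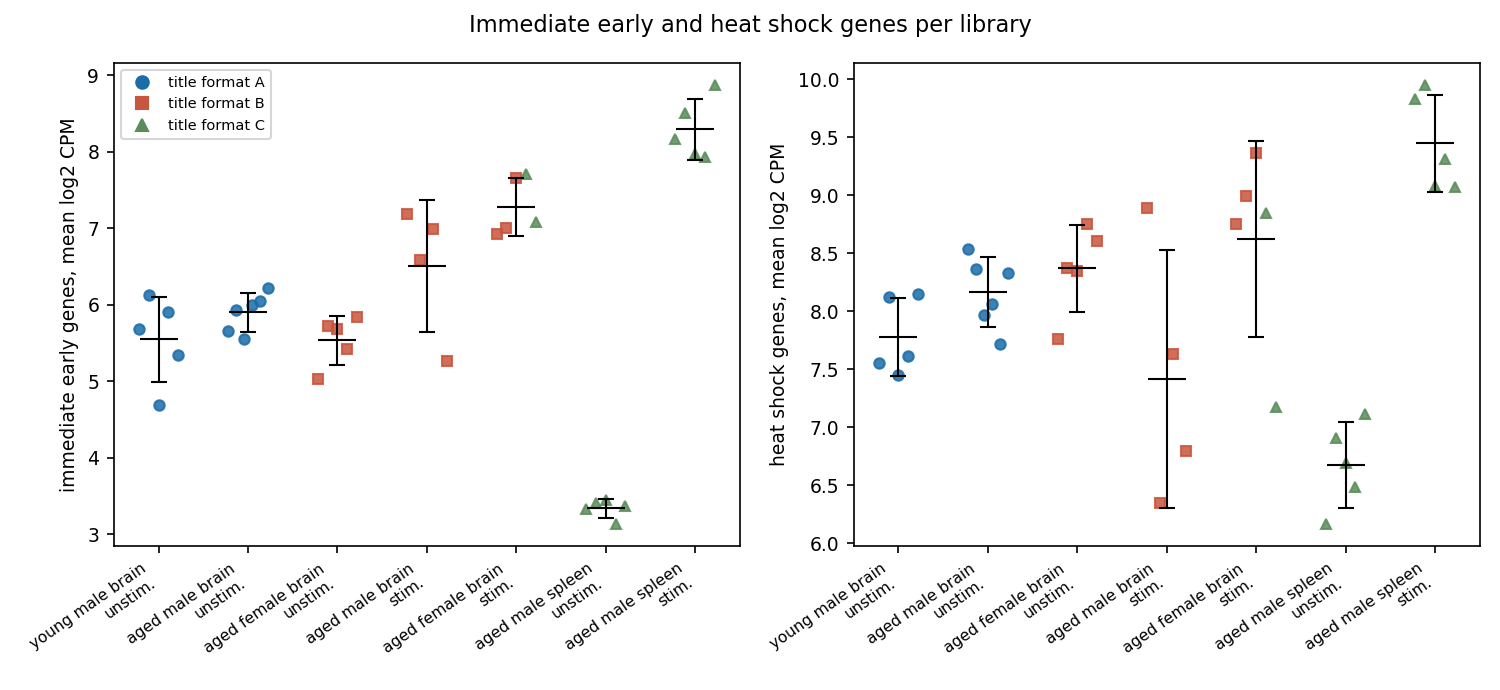
Mean log2 CPM over the immediate early genes (left) and heat shock genes (right) in each of 35 libraries; horizontal bars are group means and error bars 1 SD, and symbols give the title format. Unstimulated spleen libraries reached at most 3.44 for immediate early genes, below every unstimulated brain library (lowest 4.69).

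Aged and young male brain cells were compared to ask whether age changes the brain CD8 T cell programme. No gene differed past the threshold. Nr4a2, an immediate early gene, was at 550 ± 258 CPM in aged (n = 6) and 208 ± 94.6 CPM in young cells (n = 5), a log2 fold change of 1.40 ± 0.45 (adjusted p = 0.84), and Tox, a transcription factor of chronically stimulated T cells, had 1.81 ± 0.63 (adjusted p = 0.92). Tcf7, a transcription factor of naive and memory T cells, was at 114 ± 50.3 CPM in aged and 276 ± 253 CPM in young cells (-1.28 ± 0.56, adjusted p = 0.99), with replicate 3 of the young group at 717 CPM and a mean of 165 CPM without it. As a list, 10 naive and central memory genes lay lower in aged cells, with 3 above 0 (camera adjusted p = 0.0064, adjusted p = 0.095 with an estimated correlation). The 22 interferon response genes lay higher, with 14 above 0 (adjusted p = 0.0084, adjusted p = 0.16 with an estimated correlation), Ifit3 at 1.89 ± 0.97 (adjusted p = 0.99). No member of either list passed, also when adjusted over the list alone. Markers of other cells lay the same way as the naive genes without passing: 4 CD4 and regulatory T cell markers had a median of -2.55 with 0 above 0, and 9 microglia markers -0.99 with 1 above 0 (both adjusted p = 0.052, adjusted p = 0.51 with an estimated correlation). Ighm, the 1 B cell marker measured, had -3.67 ± 1.26 and passed only when adjusted over its list alone (adjusted p = 0.87 over all genes). Immediate early genes Nr4a1 (0.62 ± 0.44) and Nr4a3 (0.54 ± 0.48), effector genes Ifng (1.39 ± 1.10), Gzmb (0.15 ± 0.79), Ccl5 (-0.02 ± 0.29) and Serpinb9 (1.46 ± 0.59), Klrc1 (-0.84 ± 0.52), Satb1 (-0.62 ± 0.55), Rgs1 (-0.75 ± 0.47), Inpp4b (-0.20 ± 0.45) and Ly6c2 (-0.16 ± 0.43) differed by less than the threshold allowed. So did the leucocyte genes Ptprc (-0.28 ± 0.24) and Cd3g (-0.12 ± 0.25) and the microglia marker Cst3 (-1.16 ± 0.998). Cd200r1 was at 20.1 ± 33.3 CPM in aged and 23.6 ± 51.35 CPM in young cells (-0.23 ± 1.88, adjusted p = 0.99). Single libraries held much of both, aged replicate 7 with 80.5 CPM (mean 8.04 CPM without it) and young replicate 6 with 115 CPM (0.68 CPM without it). With edgeR 0 of 8068 genes passed. An unadjusted p under 0.05 was seen for 374 genes (4.6%), DESeq2 called 72 (44 higher, 28 lower) and limma voom 0. Changes had to be large to be seen: of simulated genes with a log2 fold change of 3, the same test recovered 19%.

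Aged female and male brain cells without stimulation differed in Y-linked genes and, under some of the settings tried, in ribosomal protein genes. Ddx3y, at 127 ± 110 CPM in males (n = 6), had 0 counts in females (n = 5) and was at least 473-fold lower, Uty at least 435-fold and Kdm5d at least 293-fold lower, and Eif2s3y had a log2 fold change of -10.23 ± 1.77. Xist, at 140 ± 27.1 CPM in females, did not pass (3.94 ± 1.11, adjusted p = 0.43). The other 9 genes past the threshold encode ribosomal proteins, all lower in females. Rpl32 (-1.17 ± 0.17), Rpl21 (-1.14 ± 0.19), Rpsa (-0.97 ± 0.16), Rplp2 (-1.31 ± 0.23), Rpl6 (-0.91 ± 0.17) and Rpl13a (-0.89 ± 0.16) were named by the rule set beforehand. Ribosomal protein genes have many processed pseudogenes that share reads, so single-gene values are uncertain. Of 62 ribosomal protein genes with at least 500 CPM, all 62 lay lower in females, while the median of all genes was -0.28, or -0.16 with DESeq2 size factors. Male replicate 8 stood apart, with 11.6% of counts in ribosomal protein genes, inside the female range of 10.5% to 12.82%, against 16.8% to 18.32% in the other 5 males. The 4 CD4 and regulatory T cell markers measured lay higher in females as a list (adjusted p = 0.0052, adjusted p = 0.072 with an estimated correlation), with Il2ra at 2.99 ± 1.503 and Cd40lg at 3.31 ± 2.22, neither past the threshold. Ptprc (0.07 ± 0.24), Cd3g (-0.37 ± 0.26), Nr4a2 (-0.66 ± 0.35), Tox (-1.21 ± 0.53), Ifit3 (-1.26 ± 0.51) and Cst3 (-1.05 ± 1.32) did not pass. Cd200r1 was at 5.76 ± 9.47 CPM in females (1.61 CPM without replicate 13) and 23.2 ± 38.5 CPM in males (9.25 CPM without replicate 7; -2.01 ± 2.04, adjusted p = 1.0). In all, 13 of 8691 genes passed, all lower in females. The count was 6 with DESeq2 size factors, 44 with voom, 4 with microglia markers as a covariate and between 4, without male replicate 12, and 15 with single libraries left out. DESeq2 called 23 (13 higher) and a fit of all 35 libraries 11 (7 higher), each with 4 of the 13 genes, and the ribosomal genes named here were not among them. With at least 10 counts in every library, which leaves out the Y-linked genes, edgeR called 0 of 3142, and 228 had an unadjusted p under 0.05. Of the 10 named genes past the threshold, Rpl13a, Rpl21, Rpl6, Rplp2, Rpsa, Eif2s3y and Kdm5d lost it without 1 library, 6 of them without male replicate 10. Female libraries fell in title format B and male libraries in format A, so sex cannot be told apart from this inferred split of titles written alike.

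Stimulation of aged male spleen cells changed 2080 of 11107 genes, 1400 higher and 680 lower, and genes of T cell activation were among those with the highest log2 fold changes. Nr4a1 rose from 5.39 ± 1.47 to 3054 ± 802 CPM (SD, n = 5 and 5; log2 fold change 9.15 ± 0.29, adjusted p = 4.9e-10). Egr1, a zinc finger immediate early factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), rose from 14.9 ± 2.57 to 3503 ± 362 CPM (7.88 ± 0.18, adjusted p = 1.8e-11). Ifng rose from 18.2 ± 4.82 to 3034 ± 964 CPM (7.38 ± 0.29), and Cd69 from 23.1 ± 12.2 to 1434 ± 614 CPM (5.95 ± 0.47). All 25 immediate early genes rose, also 25 when adjusted over the list alone (adjusted p = 1.6e-148, and 0.00093 with an estimated correlation), among them Atf3 (11.999 ± 1.05), Nr4a3 (8.74 ± 0.54) and Nr4a2 (7.70 ± 0.30). All 12 heat shock genes rose, also when adjusted over the list alone (adjusted p = 8.3e-39, and 0.0070 with an estimated correlation), with Hspa1a from 65.4 ± 58.4 to 6422 ± 2274 CPM (6.62 ± 0.83), Hspa1b at 6.23 ± 0.49 and Dnajb1 at 4.38 ± 0.24. Of 23 NF-kB and NFAT target genes 18 rose, and 21 when adjusted over the list alone (adjusted p = 1.7e-33, and 0.045 with an estimated correlation), led by Nfkbid (6.99 ± 0.43), Nfkbiz (5.64 ± 0.28) and Tnfaip3 (5.51 ± 0.17). Cytokine and chemokine genes had 12 of 17 higher, and 13 higher with 1 lower when adjusted over the list alone (adjusted p = 1.5e-20, and 0.015 with an estimated correlation). Among them Il10, an anti-inflammatory cytokine gene, rose from 0.27 ± 0.46 (0.0605 without replicate 32) to 67.1 ± 19.5 CPM (7.95 ± 0.67), Il21 by 7.61 ± 0.78 and the chemokine gene Ccl4 by 6.66 ± 0.34.

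Of the other groups, some had members higher and lower after stimulation of spleen cells, and the inhibitory receptor and cytotoxic lists had only higher ones. Tissue residency genes had 9 of 19 higher and 3 lower, the same when adjusted over the list alone (adjusted p = 1.3e-08, and 0.0065 with an estimated correlation; median 0.08, mean 0.93), with Cd69 and Bhlhe40 (3.88 ± 0.23) up and Itga1 (-2.37 ± 0.69) and Cxcr6 (-1.14 ± 0.25) down. Inhibitory receptor genes had 4 of 20 higher, also 4 when adjusted over the list alone (adjusted p = 0.00031, and 0.015 with an estimated correlation), including Ctla4 (3.87 ± 0.22), Lilrb4 (2.28 ± 0.41) and Pdcd1 (2.21 ± 0.37). Cell death genes had 10 of 17 higher and 2 lower (adjusted p = 0.00029, adjusted p = 0.22 with an estimated correlation), with the stress-response genes Cdkn1a (5.83 ± 0.78), Gadd45a (5.16 ± 0.75) and Pmaip1 (3.09 ± 0.23) up and Bcl2 (-1.196 ± 0.20) and Casp8 (-0.70 ± 0.18) down. Egress and trafficking receptors fell more often than they rose. Circulation and egress genes had 6 of 16 lower and 2 higher, and 9 lower when adjusted over the list alone (adjusted p = 0.036, adjusted p = 0.34 with an estimated correlation), with S1pr4 (-1.86 ± 0.36), S1pr1 (-1.38 ± 0.17) and Ly6c2 (-1.06 ± 0.23) down and Ccr7 (2.50 ± 0.39) and Eomes (0.96 ± 0.19) up. Trafficking receptors had 7 of 21 lower and 1 higher, and 8 lower when adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.069 with an estimated correlation), with Cxcr3 (-1.37 ± 0.18) down and Cxcr4 (2.08 ± 0.23) up. Interferon response genes had 6 of 22 lower, Ifit3 (-1.46 ± 0.39), Ifit1 (-1.36 ± 0.43) and Rtp4 (-1.31 ± 0.33) among them, and 2 higher, Isg15 (1.98 ± 0.44) and Ifih1 (0.91 ± 0.21; adjusted p = 0.076). Cytotoxic genes had 3 of 15 higher, Srgn (2.09 ± 0.20), Fasl (1.55 ± 0.29) and Serpinb9 (0.69 ± 0.22; adjusted p = 0.76). Naive and central memory genes had 2 higher, Ccr7 and Satb1 (1.45 ± 0.28), and 2 lower, Il7r (-0.84 ± 0.20) and Lef1 (-0.71 ± 0.22; adjusted p = 0.74). Glycolysis genes had Hk2 (3.15 ± 0.61) and Gapdh (0.51 ± 0.12) up and Eno1 (-0.44 ± 0.14) down of 15 (adjusted p = 0.47).

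Markers of other cells also differed in stimulated spleen libraries, at low levels. B cell markers had 6 of 9 higher, and 8 when adjusted over the list alone (adjusted p = 9.7e-05, adjusted p = 0.058 with an estimated correlation), with Pax5 (3.11 ± 0.61) and Fcer2a (2.81 ± 0.74). The antigen presentation genes H2-Aa (1.13 ± 0.32) and Cd74 (0.84 ± 0.22) were higher as well. Microglia and macrophage markers had 1 of 9 lower, Csf1r (-2.30 ± 0.57; adjusted p = 0.033, adjusted p = 0.16 with an estimated correlation). Genes with low log2 fold changes included the macrophage gene Mrc1 (-3.46 ± 0.94), the adhesion gene Vcam1 (-3.44 ± 0.82), Lrp1 (-3.14 ± 0.50), Exoc8 (-2.81 ± 0.41) and C1d (-2.64 ± 0.71). Cd200r1 was at 3.44 ± 2.25 CPM stimulated and 5.99 ± 2.13 CPM unstimulated (-0.80 ± 0.62, adjusted p = 0.42). Both groups had title format C. The count was 1144 with a log2 fold change of at least 1 required and 53 in a fit of all 35 libraries, whose shared spread includes the brain groups. Of 58 named genes past the threshold, 48 stayed past it without each library in turn.

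**Figure D3:**
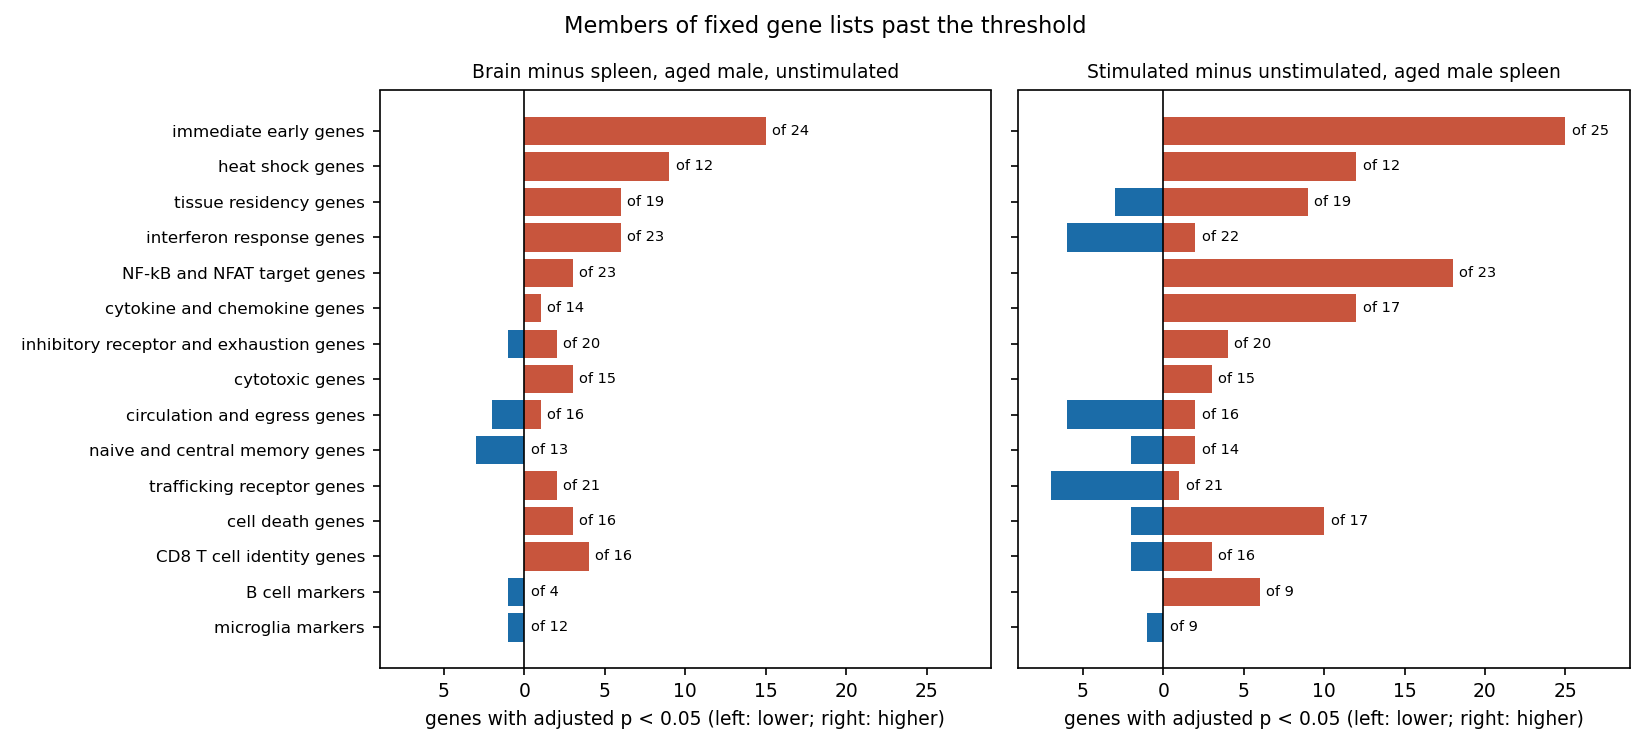
Number of genes with an adjusted p under 0.05 in 15 gene lists, higher to the right and lower to the left, for brain against spleen in unstimulated aged males and for stimulation in aged male spleen; text gives the number of members measured. All 25 immediate early genes and all 12 heat shock genes rose in stimulated spleen, and 15 of 24 and 9 of 12 were higher in unstimulated brain.

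Stimulated female brain cells had higher chemokine, cytokine and early response genes than unstimulated ones, in libraries whose mitochondrial share was 58.6% ± 10.8 against 10.5% ± 1.65. The chemokine gene Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) was at 951 ± 616 CPM stimulated and 4.29 ± 5.26 CPM unstimulated (2.18 CPM without replicate 13; SD, n = 5 and 5; 7.79 ± 1.42, adjusted p = 0.011). Tnf, the tumour necrosis factor gene, was at 743 ± 464 CPM against 10.4 ± 7.72 CPM (6.15 ± 1.19), and Ccl4 had 4.07 ± 0.80. Of 11 cytokine and chemokine genes 4 were higher, also 4 when adjusted over the list alone (adjusted p = 1.4e-05, and 0.034 with an estimated correlation). Of 23 immediate early genes 11 were higher, and 16 when adjusted over the list alone (adjusted p = 1.9e-15, and 0.034 with an estimated correlation). They included Egr2, at 533 ± 264 CPM against 11.2 ± 6.63 CPM (5.57 ± 1.18), Egr3 (4.35 ± 1.15), Gadd45b (4.36 ± 1.21) and Nr4a2 (2.24 ± 0.53). NF-kB and NFAT target genes had 3 of 17 higher, Nfkbia (3.82 ± 0.81), Nfkbid (3.41 ± 0.96) and Nfkbiz (3.27 ± 0.86; adjusted p = 3.2e-05, adjusted p = 0.078 with an estimated correlation). Heat shock genes had 2 of 12 higher, and 3 when adjusted over the list alone (adjusted p = 0.00039, adjusted p = 0.19 with an estimated correlation), Hspa1b from 2120 ± 1203 to 17800 ± 6676 CPM (3.07 ± 0.46) and Hspa1a at 2.82 ± 0.43. Oligodendrocyte markers had 1 of 3 higher, also 1 when adjusted over the list alone (adjusted p = 0.0080, adjusted p = 0.078 with an estimated correlation). Neuron markers lay higher as a list of 3 (adjusted p = 0.027, adjusted p = 0.11 with an estimated correlation), with Snhg11 at 6.36 ± 2.09 (adjusted p = 0.10) and Thy1 at -0.79 ± 0.75. Other high log2 fold changes were Frrs1l (9.19 ± 1.96), Nav2 (8.65 ± 2.03), Ttr (7.75 ± 1.88), Mylk4 (7.58 ± 1.63) and Rgs7bp (7.57 ± 1.62). Lower were the integrin genes Itga1 (-6.28 ± 1.33) and Itgb2 (-2.72 ± 0.73) and the activating receptor gene Klrk1 (-9.06 ± 1.80). With 0 counts in all 5 stimulated libraries, Hist1h2af was at least 199-fold lower, Slfn9 at least 130-fold, Rwdd1 at least 87.9-fold, Casp8ap2 at least 80.5-fold, Eif1ax at least 78.4-fold and Zfp26 at least 71.4-fold. The T cell receptor constant gene Trbc2 was at least 48.8-fold lower, Tnfsf10 at least 41.4-fold and Entpd1 at least 35.8-fold. Xist was at 98.0 ± 106 CPM against 99.4 ± 19.1 CPM (-0.02 ± 1.18), and Cd200r1 was not tested because it had too few counts. In all, 384 of 6305 genes passed, 121 higher and 263 lower. Of 149 tested genes with 0 counts in all 5 stimulated libraries, 146 passed. The count was 875 with DESeq2, 1360 with voom and 135 within title format B. The balance turned among the 921 genes with at least 10 counts in every library, where 97 were higher and 45 lower. It also turned without unstimulated replicate 13 (36 higher, 15 lower), 14 (35 and 18), 16 (35 and 14) or 17 (44 and 24), and 24 of 30 named genes lost the threshold without replicate 16. Among these were Tnf (5.97, adjusted p = 0.052), Ccl4 (4.15, adjusted p = 0.052), Egr2 (5.59, adjusted p = 0.058), Egr3, Gadd45b, Nr4a2, Nfkbia, Nfkbid and Nfkbiz. Ccl3, Hspa1a, Hspa1b, Hist1h2af and Eif1ax stayed past it without each library in turn.

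Stimulated male brain cells had higher Ccl3, Tnf and Egr genes, in libraries whose mitochondrial share was 56.3% ± 13.2 against 9.88% ± 0.456. Ccl3 was at 967 ± 712 CPM stimulated (SD, n = 4) and 12.3 ± 16.3 CPM unstimulated (n = 6; 6.30 ± 1.43, adjusted p = 0.0069), or 612 CPM without stimulated replicate 20 and 6.08 CPM without unstimulated replicate 11, and Tnf at 651 ± 372 CPM against 31.5 ± 21.3 CPM (4.37 ± 1.06). Of 23 immediate early genes 4 were higher over all genes and 0 when adjusted over the list alone, including Egr3, at 354 ± 163 CPM against 14.7 ± 10.9 CPM (4.59 ± 1.29), Atf3 (4.29 ± 1.42) and Egr2 (3.74 ± 1.31; adjusted p = 3.2e-12, adjusted p = 0.070 with an estimated correlation). Cytokine and chemokine genes had 2 of 12 higher (adjusted p = 1.4e-05, adjusted p = 0.070 with an estimated correlation), NF-kB and NFAT target genes 1 of 19 over all genes and 0 when adjusted over the list alone, Nfkbia (2.96 ± 1.09; adjusted p = 0.00015, adjusted p = 0.070 with an estimated correlation), and heat shock genes 2 of 12 (adjusted p = 0.00016, adjusted p = 0.14 with an estimated correlation). Hspa1b went from 1223 ± 673 to 8223 ± 3131 CPM (2.75 ± 0.56), and Hspa1a had 2.46 ± 0.50. Cytotoxic genes had 8 of 14 lower, the same when adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.078 with an estimated correlation), with 0 counts of Serpinb9, at least 180-fold lower, of Tnfsf10, at least 65.3-fold, and of Gzmk, at least 63.2-fold. Interferon response genes had 12 of 22 lower, and 14 when adjusted over the list alone (adjusted p = 0.021, adjusted p = 0.13 with an estimated correlation), with 0 counts of Zbp1, at least 90.9-fold lower, Ifit2, at least 55.8-fold, and Rtp4, at least 45.2-fold. The 3 astrocyte (adjusted p = 0.021, adjusted p = 0.14 with an estimated correlation) and 3 neuron markers (adjusted p = 0.021, adjusted p = 0.12 with an estimated correlation) lay higher as lists with no member past the threshold. CD8 T cell identity genes had 6 of 16 lower, against 2743 of 7540 among all genes, and 7 when adjusted over the list alone (adjusted p = 0.29), with Trbc2 at least 67.9-fold lower, Cd3d at -6.26 ± 1.92 and Cd8b1 at -5.07 ± 1.78. Cxcr4 (-11.09 ± 1.93), Ly6c2 (-11.62 ± 1.88), Lef1, at least 74.1-fold, and Ctla4, at least 23.6-fold, were lower too. Genes with high log2 fold changes included Pygo1 (8.75 ± 1.96), Stxbp6 (8.26 ± 1.84), Usp17la (8.16 ± 1.71), Slc17a9 (8.13 ± 1.81), Tfap2a (8.07 ± 1.78) and Muc19 (7.56 ± 1.84), with Igfbp4 at 4.75 ± 1.59. Genes with 0 counts in all 4 stimulated libraries included Hist1h2ao, at least 646-fold lower, Serpina3g (281-fold), Gdi2 (272-fold), Rps16 (249-fold), Taf15 (244-fold) and Inpp4b (220-fold). The histone and ribosomal members share reads with near-identical copies. In all, 2875 of 7540 genes passed, 132 higher and 2743 lower. Of 2187 tested genes with 0 counts in stimulated cells 2106 were among the lower ones. The median over all genes tested was -2.62. Only 494 genes had at least 10 counts in every library, of which 103 passed, 75 higher and 28 lower. Of 34 named genes past the threshold, Atf3, Egr2, Nfkbia, Cd8b1 and Igfbp4 lost it without 1 library, the first 4 of them without unstimulated replicate 10. Unstimulated libraries fell in title format A and stimulated ones in format B, a split inferred from the numbers after S in titles written alike. Cd200r1 was not tested because it had too few counts.

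**Figure D4:**
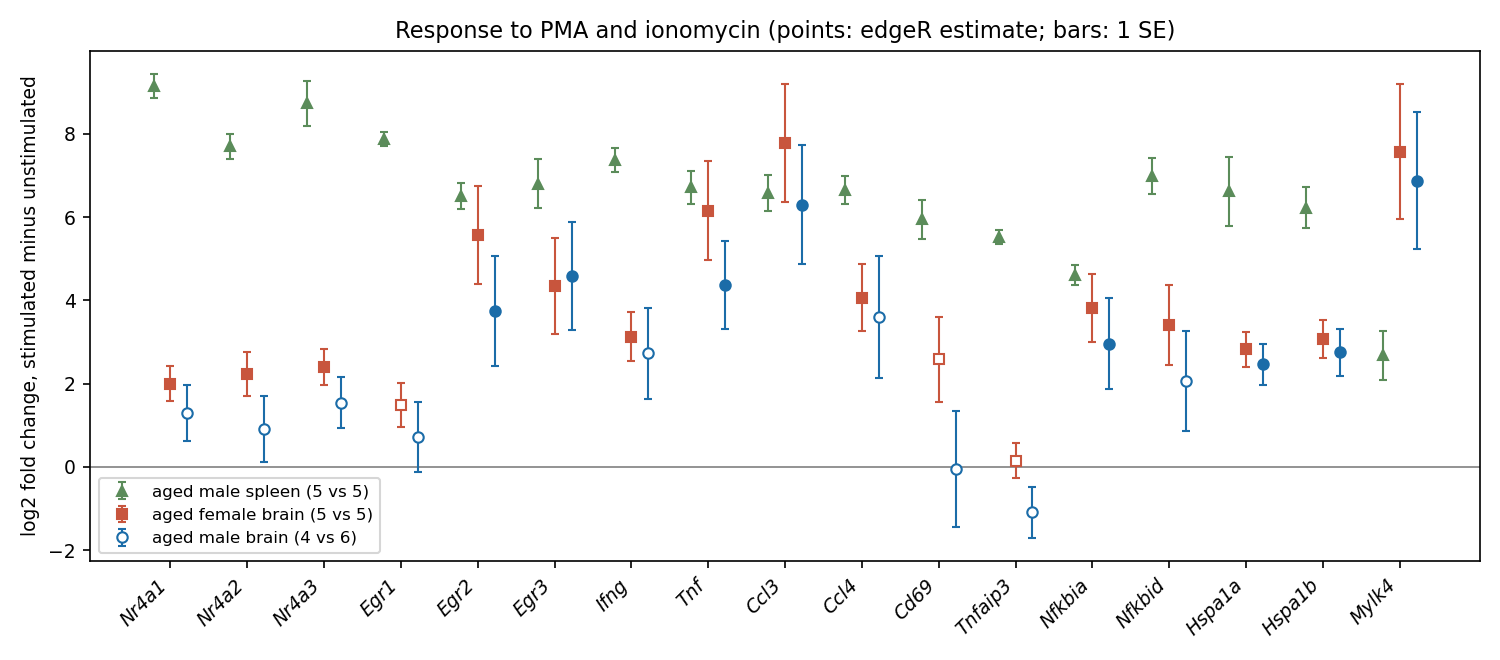
Log2 fold change (stimulated minus unstimulated, edgeR) of 17 genes in aged male spleen, aged female brain and aged male brain; error bars are 1 SE and filled points have an adjusted p under 0.05. Immediate early genes such as Nr4a1 rose by 9.15 in spleen, while Ccl3, Tnf and Hspa1b rose in all 3 comparisons.

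Stimulated brain and spleen cells of aged males differed mainly in genes that brain libraries no longer registered. Of 9135 genes tested 4434 passed, 166 higher and 4268 lower in brain. Of 3444 tested genes with 0 counts in all 4 brain libraries, 3386 passed, so nearly every gene missed in brain counted as lower. The median over all genes was -3.02. Among the higher genes were Snhg11 (6.01 ± 1.26), Meg3 (5.80 ± 1.42), the astrocyte marker Slc1a3 (3.47 ± 1.09) and the microglia marker Siglech (3.55 ± 1.02). Without 1 library Slc1a3 (1.74 without brain replicate 20), Siglech (2.38 without brain replicate 22) and Myc lost the threshold. Microglia (adjusted p = 0.51) and oligodendrocyte markers (adjusted p = 0.32) each had 1 of 3 higher and 1 lower, also when adjusted over the list alone. Astrocyte markers had 2 of 3 higher (adjusted p = 0.0081, adjusted p = 0.21 with an estimated correlation) and neuron markers 1 of 3 (adjusted p = 0.016, adjusted p = 0.21 with an estimated correlation), the same counts when adjusted over the list alone. Mlip (5.07 ± 0.88), Mylk4 (4.97 ± 0.84), Wnt4 (4.50 ± 0.67) and Igfbp4 (3.35 ± 0.79) were also higher. Of 25 immediate early genes 4 were lower, Ier3, at least 16.6-fold, Btg2 (-4.01 ± 1.01) and Myc (-2.31 ± 0.75) among them, and 3 when adjusted over the list alone. That list's median was -0.54, yet its test pointed up (adjusted p = 0.0081, adjusted p = 0.59 with an estimated correlation), because it compares with all other genes. The 12 heat shock genes had none past the threshold and likewise tested up (adjusted p = 0.017, adjusted p = 0.59 with an estimated correlation), with Hspa1b at 8535 ± 3456 CPM in brain and 4186 ± 1326 CPM in spleen (1.03 ± 0.42, adjusted p = 0.069) and Hspa8 at -0.69 ± 0.53. Tnfaip3 was at 739 ± 231 CPM against 2831 ± 606 CPM (-1.94 ± 0.37, adjusted p = 0.0016). With 0 counts in brain, Bcl2a1d was at least 227-fold lower, Taf15 196-fold, Rps16 179-fold, Gdi2 176-fold, Eif2s2 146-fold, Sarnp 136-fold and Ighm 131-fold. The T cell genes Serpinb9 (at least 51.9-fold), Ctla4 (51.2-fold), Inpp4b (49.9-fold), Gzmk (45.4-fold), Lef1 (40.1-fold), Il10 (27.2-fold), Ccr7 (25.97-fold) and Prf1 (16.96-fold) were likewise at 0. Cd200r1 had 0 counts in brain and 2.28 ± 1.48 CPM in spleen, at least 1.40-fold lower (adjusted p = 0.029). Brain libraries had title format B and spleen format C. With format as a term, estimated through the stimulated female brain libraries, edgeR called 0 genes, and 2623 had an unadjusted p under 0.05. Within format C, where the 2 stimulated female brain libraries stand in for the male ones, 4896 passed (684 higher, 4212 lower), of which 2779 were also among the 4434, 82 of them in the opposite direction. Of 551 genes with at least 10 counts in every library 143 passed, 100 higher and 43 lower.

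Stimulated female and male brain cells were not told apart gene by gene. Ccl4 was at 391 ± 179 CPM in females (n = 5) and 223 ± 110 CPM in males (n = 4; 0.81 ± 0.88), Nr4a2 had 0.26 ± 0.74, Cd69 0.91 ± 1.59, Bhlhe40 -0.63 ± 1.02, Ccl5 0.36 ± 1.24 and Tox 0.18 ± 1.69. Cd3g (2.48 ± 1.55), Ptprc (0.45 ± 1.01), Siglech (-0.90 ± 1.52) and Xist (4.09 ± 2.41) did not pass either, all with an adjusted p of 1.0. With edgeR 0 of 3159 genes passed and 158 (5.0%) had an unadjusted p under 0.05, while DESeq2 called 90 (82 higher, 8 lower), voom 0 and a fit of all 35 libraries 2560. Y-linked genes and Cd200r1 had too few counts to be tested.

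The response to stimulation differed between brain and spleen of aged males by a direct test of the difference. With the difference coded as brain response minus spleen response, 4577 of 12117 genes passed, 254 higher and 4323 lower, around a median of -4.04 that DESeq2 size factors moved to -3.33. Of 25 immediate early genes 17 had a negative difference, a response lower in brain than in spleen, and 19 when adjusted over the list alone (adjusted p = 6.1e-08, adjusted p = 0.062 with an estimated correlation). Unstimulated brain cells started higher, so a negative difference need not mean lower levels after stimulation. The list's mean log2 CPM went from 5.90 to 6.50 in brain and from 3.34 to 8.29 in spleen. The unstimulated levels also came from title format A in brain and C in spleen. Nr4a1 went from 927 to 2047 CPM in brain and from 4.52 to 2557 CPM in spleen (-7.996 ± 0.79), Tnfaip3 from 1866 to 801 CPM and from 78.7 to 3587 CPM (-6.73 ± 0.56), and Ifng from 168 to 1066 CPM and from 15.3 to 2539 CPM (-4.71 ± 1.17). Atf3 (-7.74 ± 1.81), Hspa1a (-4.28 ± 0.85), Hspa1b (-3.58 ± 0.76) and Hspd1 (-4.85 ± 1.47) followed. Cytotoxic genes had 10 of 15 lower, also 10 when adjusted over the list alone (adjusted p = 2.8e-05, and 0.019 with an estimated correlation), with Fasl at -8.43 ± 1.196. Tissue residency genes had 11 of 19 lower, also 11 when adjusted over the list alone (adjusted p = 0.0044, and 0.024 with an estimated correlation). Inhibitory receptor genes had 11 of 20 lower, and 12 when adjusted over the list alone (adjusted p = 0.0091, and 0.028 with an estimated correlation), with Pdcd1 at -4.68 ± 1.62. Interferon response genes (13 of 23 lower, adjusted p = 0.0091, adjusted p = 0.084 with an estimated correlation), CD8 T cell identity genes (9 of 16, adjusted p = 0.012, adjusted p = 0.15 with an estimated correlation) and heat shock genes (8 of 13, adjusted p = 0.046, adjusted p = 0.36 with an estimated correlation) were lower as well. Gdi2, Taf15, Rps16 and Eif2s2 had 0 counts in stimulated brain and between 302 and 405 CPM in stimulated spleen. Larger in brain were the mitochondrial genes mt-Nd4 (2.61 ± 0.40), mt-Nd5 (2.34 ± 0.40) and mt-Nd6 (2.95 ± 0.50), Cdc42bpg, Gtse1 and Il21, the last from 0 to 172 CPM in brain. Il21 turned with voom (-0.97, adjusted p = 0.91) and lost the threshold without any 1 of 6 libraries, and Gtse1 lost it without stimulated brain replicate 20 (0.78, adjusted p = 0.93). Cd200r1 went from 21.9 to 0 CPM in brain and from 5.02 to 2.90 CPM in spleen (adjusted p = 0.025, or 0.045 without unstimulated brain replicate 7). Replicates 7 and 12 held nearly all of the brain signal of Cd200r1 (97.1 and 46.8 CPM in the unstimulated comparison), and the other 4 had at most 1.60 CPM, under the floor of 3 counts in the shallowest stimulated library. A split of the libraries that kept the stimulated groups and regrouped only unstimulated ones gave 4636 genes, so a count this large does not need the real grouping of the unstimulated libraries. The count was 2770 with voom. Among 493 genes with at least 10 counts in every library the balance turned, with 84 higher and 77 lower. In male brain libraries the mitochondrial share and the inferred split between title formats A and B moved together with stimulation.

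The responses of female and male brain cells were compared in the same way, as female response minus male response. No gene list passed. Nr4a1 (0.63 ± 0.89), Nr4a3 (0.80 ± 0.87), Ifng (0.29 ± 1.27) and Ccl3 (1.36 ± 1.66) showed no difference past the threshold, and Cd200r1 had 0 counts in both stimulated groups (adjusted p = 1.0). Of 10026 genes 261 passed, 205 higher and 56 lower, around a median of 1.69 that DESeq2 size factors moved to 1.02. Taf15 and Serpina3g had 220 and 486 CPM in stimulated female brain and 0 in stimulated male brain, against 390 and 375 CPM in unstimulated females and 381 and 440 CPM in unstimulated males. Inpp4b and Ttc3 likewise had 96.4 and 238 CPM in stimulated females and 0 in stimulated males, and Hnrnpa1 had 221 and 0.19 CPM. Stimulated male libraries detected 3400 genes on average against 5578 in stimulated females. For genes at 0 in males, a different response cannot be told apart from this lower detection. The male response also ran from title format A to B, while unstimulated females had format B and stimulated ones B or C. Ipp, Gtse1 and Hist1h2af had 0 counts in stimulated females and 117, 102 and 110 CPM in stimulated males, with Rps24-ps3 at 0.18 and 242 CPM and Aph1a at 0.039 and 28.4 CPM. Of the 10 named genes past the threshold, Aph1a, Gtse1 and Ipp lost it without 1 library, 2 of them without stimulated male replicate 19. The count was 120 with DESeq2 size factors, of which 60.0% were higher against 78.5%, 1550 with DESeq2, 46 with voom, 0 of 380 genes with at least 10 counts in every library, and 23 without female unstimulated replicate 16. It also fell to 149 or fewer without any other unstimulated female or male library, and to 75 and 96 without stimulated male replicates 20 and 22.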

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

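The tests of title format for immediate early genes, heat shock genes, detected genes and the mitochondrial share were chosen after the results were seen. So were those of other brain cells and of stimulation alone. The test of other brain cells replaced a planned one after the result of that one was seen. That of title format for detected genes also replaced a planned one. The other tests were planned. Of 113 sets of values, 17 held a library that stood apart from its group, by its gap to the nearest library relative to the group's range. The nominal chance share is 1 in 20. Many sets are skewed CPM values of single genes and sets share libraries, so chance may give more, and 17 need not be an excess. In stimulated spleen, replicate 40 had a mitochondrial share of 20.8% (nearest 15.6%) and 1857 CPM of Hspa1b (nearest 4330). In unstimulated spleen, replicate 33 had 14.7 M counts (nearest 10.2) with 22.4% of them in the 20 most abundant genes (nearest 26.5%), and replicate 32 had a mean log2 CPM of microglia markers of 1.10 (nearest 0.71) and 1.09 CPM of Il10 (nearest 0.16). In young brain, replicate 6 had a mitochondrial share of 10.1% (nearest 8.78%) and 115 CPM of Cd200r1 (nearest 1.71), and replicate 3 had 717 CPM of Tcf7 (nearest 257). In unstimulated aged male brain, replicate 8 had 2471 CPM of Nr4a1 (nearest 1162) and 1128 CPM of Cd69 (nearest 229.8), and replicate 11 had 43.2 CPM of Ccl3 (nearest 16.1). In unstimulated female brain, replicate 13 had 22.4 CPM of Cd200r1 (nearest 4.59). In stimulated female brain, replicate 27 had a mean log2 CPM of heat shock genes of 7.17 (nearest 8.75) and replicate 25 had 1551 CPM of Tnf (nearest 717.5). In stimulated male brain, replicate 20 had 2032 CPM of Ccl3 (nearest 673) and 598.5 CPM of Egr3 (nearest 275).

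Between tissues, the test of the difference in response passed for 4577 genes. Fitted log2 differences, brain response minus spleen response, were 2.61 for mt-Nd4, 2.34 for mt-Nd5, 2.95 for mt-Nd6, 12.38 for Cdc42bpg, 14.24 for Gtse1 and 6.24 for Il21. They were -6.73 for Tnfaip3, -7.996 for Nr4a1, -7.74 for Atf3, -4.71 for Ifng, -4.85 for Hspd1, -4.28 for Hspa1a, -3.58 for Hspa1b, -4.68 for Pdcd1, -8.43 for Fasl and -10.24 for Cd200r1. Gdi2 (-15.83), Taf15 (-16.10), Rps16 (-16.23) and Eif2s2 (-15.91) had 0 counts in stimulated brain. Between sexes, 261 genes passed, with fitted differences, female response minus male response, of 14.31 for Taf15, 15.72 for Serpina3g, 10.27 for Hnrnpa1, 13.61 for Inpp4b, 14.36 for Ttc3, -17.52 for Rps24-ps3, -21.99 for Ipp, -12.41 for Hist1h2af, -19.17 for Aph1a and -20.19 for Gtse1. Where a group is at 0, fitted values depend on the prior count and are no bounds.

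Immediate early and heat shock genes were higher in unstimulated brain than spleen cells, by 2.56 and 1.49 on the mean log2 CPM scale in aged males, 2.2 and 1.70 in aged females and 2.21 and 1.11 in young males against the same spleen libraries. For immediate early genes, title format C differed from B by only 0.197 (SE 0.382) in stimulated female brain, or -0.118 and 0.511 without replicate 26 or 27. Stimulation raised these genes there, from a mean of 5.54 to 7.28, so the values cannot show a format difference in unstimulated cells. Formats A and C share no group, and format stays open. RNA of microglia, oligodendrocytes, astrocytes, neurons or choroid plexus is argued against as the whole source, since it would make the scores rise with its markers: within the 3 unstimulated brain groups, the immediate early score had slopes of -0.11 (SE 0.035) on the log2 CPM of 22 markers under 1 CPM in every unstimulated spleen library, which ran from 0 to 151.63 CPM, and -0.086 (SE 0.036) on Ttr, and the heat shock score -0.005 (SE 0.04) and -0.062 (SE 0.033). For heat shock genes the format difference in stimulated female brain was -1.027 (SE 0.664), -1.86 without replicate 26 and -0.192 without replicate 27. Format stays a candidate source there too, with a difference that rests on replicate 27. Time and handling during isolation from brain may differ from spleen and were not tested, and neither was the tissue itself, so both stay open.

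Stimulated brain libraries detected fewer genes and held a larger mitochondrial share. Lower depth is argued against: after thinning to the nuclear counts of the stimulated libraries, 10 of 11 unstimulated libraries still detected more nuclear genes than every stimulated library of their sex. With stimulation the share rose by 4.57 percentage points in spleen against 46.4 in male and 48.0 in female brain. This argues against stimulation alone, acting alike in both tissues, as the whole cause of the share. An effect of stimulation particular to brain cells would give the same values and stays open. Within title format B the lowest stimulated library lay 25.71 points above the highest unstimulated one, which argues against format as the whole cause of the share. Format as the whole cause of fewer detected genes is argued against too, since among female format B libraries the unstimulated ones detected 3926 more (SE 1457, n = 5 and 3; 3138 to 4701 with single libraries left out), although the lowest of them (6456) lay under the highest stimulated one (6523). Fewer cells, or more dying cells, after stimulation of brain cells could give both changes, and neither was measured.

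Ribosomal protein genes were lower in female than male unstimulated brain libraries, with a median log2 fold change of -1.17 over the 9 genes past the threshold and -0.807 over 62 abundant ones. Other nuclear genes of that level, 218 in number, had a median of -0.276, so scaling between the groups may account for part and stays open. In stimulated title format B libraries of both sexes the 9 genes had a median of 0.265 with a median SE of 0.905, too wide to decide on format. With microglia markers as a covariate the median was -1.13 (median SE 0.188 against 0.171). The same genes differed by 0.014 between aged and young males, both in title format A. In aged male brain minus spleen, format A against C, their median was 1.11. Sex and the inferred split between title formats A and B cannot be told apart here.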

How the results depend on the processing

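The requirement of at least 10 counts in every library and that of detection in every library of a group were added after the data were seen. No paired analysis was run. Replicate numbers do not repeat between groups, and the labels do not say whether stimulated and unstimulated cells came from the same animals. Over 309 gene results named in the text or by the naming rule, 3235 values under other settings gave 2980 in the same direction and on the same side of the threshold, 212 weaker, 15 stronger, 27 sign changes among uncalled values and 1 reversal, Il21 in the tissue difference of the response (-0.97 with voom). Counts of genes past the threshold stayed within 1.5 times of the reported ones except as follows, and the cause was not tested. With DESeq2 the counts were 72 for age, 23 for sex unstimulated, 90 for sex stimulated, 875 for stimulation in female brain and 1550 for the sex difference of the response. With voom they were 1615 for tissue unstimulated, 44 for sex unstimulated, 1360 for female brain stimulation, 2770 for the tissue difference of the response and 46 for the sex difference. With DESeq2 size factors they were 6 for sex unstimulated and 120 (72 higher, 48 lower) for the sex difference. In a fit of all 35 libraries they were 1 for age, 2560 for sex stimulated, 53 for spleen stimulation, 2549 and 5018 for female and male brain stimulation and 2154 for the sex difference. Without a low-count filter they were 25 for age, 1677 for tissue unstimulated, 29 and 21 for sex unstimulated and stimulated and 704 for female brain stimulation. With at least 10 counts in every library, which leaves fewer genes to test, they were 1 for age, 245 and 143 for tissue unstimulated and stimulated, 0 for sex unstimulated, 142 and 103 for female and male brain stimulation, 161 for the tissue difference and 0 for the sex difference. With detection in every library of a group the sex difference gave 422. A log2 fold change of at least 1 left 1144 in spleen stimulation, microglia markers as a covariate left 4 for sex unstimulated, title format as a term left 0 for tissue stimulated, and title format B alone left 135 for female brain stimulation. Of 55 gene list calls over the 10 comparisons 17 held with an estimated correlation.

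Leaving out each library in turn gave 0 to 1 genes for age (1 without replicate 12), 677 to 1015 for tissue unstimulated, 3482 to 5981 for tissue stimulated, 4 to 15 for sex unstimulated, 0 to 1 for sex stimulated (1 without replicate 19), 1554 to 2340 for spleen stimulation, 49 to 596 for female brain stimulation, 2108 to 2884 for male brain stimulation, 4038 to 4877 for the tissue difference and 23 to 377 for the sex difference. For sex unstimulated the count was 7, 8 and 6 without female replicates 14, 16 and 17, and 5, 6, 4, 6 and 7 without male replicates 10, 11, 12, 7 and 9. For female brain stimulation it was 251 and 194 without stimulated replicates 24 and 27. For the sex difference it was 59, 46, 42 and 37 without female replicates 13, 14, 15 and 17. DESeq2 size factors moved the median log2 fold change of all genes from -0.28 to -0.16 for sex unstimulated, 0.32 to 0.06 for sex stimulated, -2.62 to -2.46 for male brain stimulation, -4.04 to -3.33 for the tissue difference and 1.69 to 1.02 for the sex difference. Depth is 1 limit of the stimulated brain comparisons, where only 494 genes had at least 10 counts in every male brain library and 921 in every female one. It is not the whole one, since unstimulated male libraries thinned to the nuclear counts of the stimulated ones detected 8219 nuclear genes on average, against 3384.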

Other observations

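The gene families here, taken as symbols with a shared stem and at least 15 tested members, were chosen and tested after the data were seen, with a one-sided Fisher's exact test adjusted over the stems of a comparison. This test treats the genes of a family as independent, although they can move together. Its p-values are therefore too small and do not measure the spread between libraries. Genes of the translation machinery were over-represented among genes that rose in stimulated spleen after scaling, while the ribosomal protein share of all counts was 13.774% stimulated and 13.768% unstimulated. Of 75 genes with the stem Rpl, for large ribosomal subunit proteins, 46 (61.3%) rose against 12.6% of all genes (adjusted p = 4.0e-21, median log2 fold change 0.62), and of 56 with the stem Rps, for the small subunit, 34 rose (60.7%, adjusted p = 1.7e-15, median 0.64). Of 54 translation initiation genes with the stem Eif 17 rose (31.5%, adjusted p = 0.0080, median 0.33), and all 16 tested mitochondrially encoded genes rose (adjusted p = 1.8e-13, median 0.97). Ribosomal protein genes were also over-represented among genes higher in unstimulated brain than spleen, with 22 of 68 Rpl (32.4% against 3.4% of all genes, adjusted p = 2.7e-14, median 0.72) and 15 of 53 Rps genes (28.3%, adjusted p = 7.9e-09), and so were histone genes, with 11 of 65 (16.9%, adjusted p = 0.00026, median 1.51), which replicating cells express. These families include pseudogenes and near copies that share reads, and medians kept their sign with DESeq2 size factors.

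In stimulated female brain, 16 of 16 mitochondrially encoded genes were higher (adjusted p = 9.3e-27, median 3.80), and in stimulated male brain 15 of 16 (adjusted p = 1.6e-24, median 3.32). Both restate the larger mitochondrial share of these libraries. Predicted genes with the stem Gm were over-represented among higher genes in both, 31 of 229 in females (13.5% against 1.9%) and 49 of 301 in males (16.3% against 1.8%), where the median in males was -0.049 and changed sign to 0.106 with DESeq2 size factors. In stimulated male brain 2743 of 7540 genes were lower, of which 2106 had 0 counts in all stimulated libraries. Nuclear genes for mitochondrial ribosomal proteins were over-represented among the lower ones, with 19 of 25 Mrpl (adjusted p = 0.0021) and 13 of 18 Mrps genes (adjusted p = 0.036). Zinc finger genes with the stem Zfp (64 of 129, adjusted p = 0.033) and Tmem genes (36 of 66, adjusted p = 0.036) were over-represented there too. The Fisher test did not match genes on level, so loss of detection cannot be told apart from a change in these families. In unstimulated aged male brain against spleen, where 444 of 11040 genes were lower, 2 families were over-represented among these. They were Gm genes (49 of 619, adjusted p = 0.00013) and T cell receptor alpha segments (6 of 34, adjusted p = 0.0499).

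Other splits of the libraries of each comparison into groups of the same sizes, 100 each with the real one included, were counted. The real split gave the most genes for tissue unstimulated (1 of 100 splits with as many genes, 814 against at most 789 in another split, which exchanged only replicate 11), tissue stimulated (1, 4434 against 16), sex unstimulated (1, 13 against 2), spleen stimulation (1, 2080 against 1), female brain stimulation (1, 384 against 1), male brain stimulation (1, 2875 against 4), and the sex difference of the response (1, 261 against 170). Regrouping libraries cannot exclude chance between animals, which the labels do not identify. For sex unstimulated, the Y-linked genes among the 13 are fixed by the sex labels. The 261 of the sex difference fell to 23 without female unstimulated replicate 16 and to 46 with voom. For the tissue difference of the response 2 of 100 splits gave as many, 4577 in the real one and 4636 in a split that kept the stimulated libraries and regrouped only unstimulated ones. That split still holds the difference between stimulated brain and stimulated spleen. On its own this difference passed for 4434 genes, of which 3386 had 0 counts in brain. How many of the 4577 genes rest on it was not counted. For age and for sex in stimulated brain the real splits gave 0 genes, which any split reaches (100 of 100), so the splits say nothing there; the highest others gave 2 and 3.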
